A study of Drosophila melanogaster with 22 samples.

How the data were processed

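The series held 22 samples of Drosophila melanogaster: 11 FAIRE-seq samples, 9 RNA-seq samples and 2 genomic DNA inputs. FAIRE-seq fixes chromatin, shears it and recovers by phenol-chloroform extraction the DNA that is not bound to protein, so that its peaks mark open chromatin. Per the labels' protocols, staged tissue for FAIRE was fixed for 10 minutes at 25 °C and chromatin was sonicated to between 500 bp and 2 kb. For RNA-seq, the labels' protocols describe total RNA from which messenger RNA was taken with oligo(dT) beads. Embryos were of the OregonR strain and all other tissues of a y;cn,bw,sp strain, per the labels. The 2 inputs had no processed values and were not used here.

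Each FAIRE sample was represented by 1 list of peaks, in which the authors gave every peak a score. Peaks were named in the manner of MACS, and the submitters' processing notes list CASAVA 1.7, Bowtie 0.12.3, MACS2 and the genome build dm3, without saying what each step did. The lists carried no header, so the scale of the score, the peak threshold, the control and the way replicates were combined were not known. Scores were therefore used to rank peaks within a list and to sum peaks of one list over an interval. The strongest regions were named by the highest score that any of the lists gave them, although scores of different lists may differ in scale. Transcript levels were deposited as FPKM in 3 tables of 3 tissues or stages each, per the file headers. FPKM stands for fragments per kilobase of transcript per 1e6 mapped fragments. How the columns had been scaled was not known, so the values may not be per 1e6 mapped fragments. The submitters' processing notes also list TopHat 1.1.4 and Cuffdiff. Each table gave 1 FPKM value per gene and tissue, with no confidence limits and no values per replicate. Upper quartiles were close within each table, between 139 and 169 over the 9 columns.

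Samples were grouped by the tissue or stage in their labels, before the data were examined, as were the comparisons, the 26 gene lists and the rule for naming genes. Peaks on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X were used, with coordinates of dm3 counted from 1. Peaks of 2 lists were called overlapping when they shared at least 1 bp. Peaks of several lists were merged into regions where they overlapped or chained through one another, which makes regions found in more lists wider. Shares of peaks and regions carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. As a background, each list was placed at random 100 times within the same arms. Since lists differed in length, overlaps were also computed over the 9975 best-scoring peaks of every list, the number in the shortest list. The arms were divided into 50 kb intervals, and in each the scores of peaks of one list that were absent from another were summed. This division was added after the data were seen. The number of sequenced reads behind each list was not known.

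For each gene, the log2 ratio of 2 columns of a table was computed as log2((FPKM + 1)/(FPKM + 1)), for genes with an FPKM of at least 5 in either column. Genes were counted as apart at a ratio of at least 2-fold. The tables held 13934 gene entries, of which 248 carried 77 names that occur more than once. These were left out, because reads shared between copies cannot be assigned, leaving 13686 genes. Of the 13763 symbols in the tables, 10018 matched current symbols of the gene name table, and names are given as in the authors' tables. Another 5 names had been turned into dates and were not matched. For each gene list, members above 0 in both columns gave a median log2 ratio. Its percentile was taken among the medians of 10000 random lists of the same size, drawn to match the members' expression in 10 bins. Genes that the authors listed at 0 in one column were counted but given no ratio, and they enter no list median.

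Genes were named by a rule fixed before the data were examined. It took the 10 largest and 10 smallest ratios of each comparison among genes with an FPKM of at least 10 in either column, and the 2 to 4 members furthest apart of each list with a member at least 2-fold apart. Ubx, Antp, Dll, dac, vg, nub, ap and hth were always taken in discs and pharate appendages, and bcd, zen, twi, eve, Ubx, elav and Mhc in embryos. The 2 highest-scoring regions of each class counted were also taken. Genes with a CG number could stay unnamed, and not every gene that the rule takes is described. Any gene outside this rule is given as chosen after its values were seen.

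With 1 pooled value per tissue, no test between tissues and no spread between replicates could be computed. Differences are given as ratios, without p-values, and "higher" and "lower" describe the values listed. The embryo, disc and pharate tables were normalised separately, so ratios between disc and pharate levels of an appendage are given as a description only. No annotation of dm3 was used here, and peaks were not assigned to genes.

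The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The expression step was run on a copy of the wing disc column, in which 200 of 7805 genes were changed 4-fold, against the column itself. All 200 were recovered. The copy carried no noise, so this checks the code only, and not how well differences between tissues are found. The overlap step gave the same call as a direct comparison of all pairs for 2000 of 2000 wing disc peaks checked. Alternatives for peaks were an overlap of at least 50%, the better-scoring 50% of each list, equal numbers of peaks and all sequences. For merged regions, in place of the 50% overlap, each peak was cut to at most its central 200 bp before merging. Alternatives for transcripts were pseudocounts of 0.1 and 5, no filter, an FPKM minimum of 20 and centring on the median. Alternatives added after the data were seen were the leaving out of each list in turn, counts restricted to genes above 0 in both columns, list medians that include genes listed at 0, repeated names kept, and intervals of 25 and 100 kb.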

Results

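Open chromatin and transcript levels were measured in Drosophila melanogaster embryos, larval imaginal discs and appendages of pharate adults. The 11 FAIRE samples were embryos at 2 to 4, 6 to 8 and 16 to 18 h after egg laying, the T3 leg, haltere, wing and eye-antennal discs and the central nervous system (CNS) of larvae of the third instar, and T3 legs, halteres and wings of pharate adults at stage P14. The 9 RNA samples were the same embryo stages, the leg, haltere and wing discs and the pharate leg, haltere and wing. Imaginal discs are the larval sacs of epithelium from which adult appendages form, and the pharate adult is the formed fly before it leaves the pupal case. Each tissue had 1 peak list or 1 FPKM column, although the labels name 2 or 3 replicates behind each, so no value below carries a spread between replicates. For the eye-antennal disc and the CNS the sample labels name 3 replicates and the series design 2.

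Pharate appendages had the most FAIRE peaks, and the eye-antennal disc and CNS the fewest. The pharate haltere list held 30374 peaks over 15.8 Mb, the pharate wing 21525 over 10.9 Mb and the pharate leg 21193 over 11.1 Mb. Among the appendage discs, the leg had 18123 peaks over 9.71 Mb, the haltere 18031 over 9.46 Mb and the wing 14285 over 7.26 Mb. The eye-antennal disc had 9975 peaks on the 6 arms over 4.64 Mb and the CNS 9990 over 4.58 Mb. Embryos had 13091 peaks at 2 to 4 h, 11096 at 6 to 8 h and 13513 at 16 to 18 h. Median peak widths ran from 358 bp at 16 to 18 h to 436 bp in the leg disc. Chromosome 4 held 41 to 45 peaks in each of the 6 appendage lists, 192 in the eye-antennal disc, 157 in the CNS and 139 to 182 in the embryo lists. The numbers of reads were not known, so list lengths also carry any difference in depth or threshold.

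The discs of the leg, haltere and wing were compared to ask how far serially related appendages share open chromatin. Most of their regions were shared. The 3 lists merged into 21489 regions, of which 11611 (54.0%, 95% interval 53.4 to 54.7) had a peak in leg, haltere and wing. A further 2611 regions had peaks in leg and haltere only, 778 in haltere and wing only and 777 in leg and wing only. Peaks in 1 disc alone made 5712 regions (26.6%, 26.0 to 27.2), 2709 in the leg, 2549 in the haltere and 454 in the wing disc. Among the better-scoring 50% of each list, 3532 regions were in 1 disc, and among equal numbers of peaks 3676. With the peaks of the full lists cut to their central 200 bp before merging, 7600 regions were in 1 disc.

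**Figure D1:**
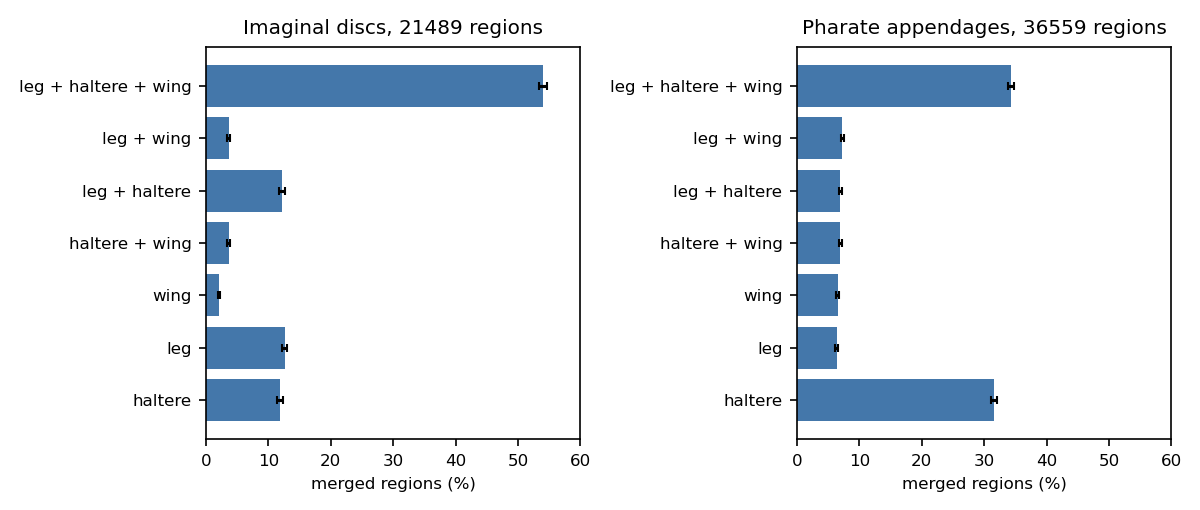
Share of merged FAIRE regions (x axis, percent) by the tissues that had a peak in them (y axis), for 21489 disc regions and 36559 pharate regions. Bars are shares and error bars exact 95% binomial intervals. Regions of leg, haltere and wing together make 54.0% in discs and 34.3% in pharate appendages, and regions of the haltere alone 11.9% and 31.6%.

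Of the wing disc peaks, 91.0% (90.6 to 91.5) overlapped a haltere disc peak and 91.1% (90.6 to 91.5) a leg disc peak, against means of 14.89% and 15.03% in random placements. In the other direction, 70.8% of haltere disc peaks and 69.7% of leg disc peaks overlapped a peak of the shorter wing disc list. Over equal numbers of best-scoring peaks the wing disc shared 81.1% with the haltere disc and 83.2% with the leg disc, and the leg disc shared 75.3% with the haltere disc. When haltere disc peaks were divided into 5 classes by score, the share found in the wing disc was 34.4% in the lowest class and 99.8% in the highest. The strongest regions of all 3 discs were at 3R 20810535 to 20811439 (score 439.6) and X 1504945 to 1506547 (413). The strongest regions of the leg disc alone lay on X, at 17710660 to 17711400 (109.8) and 17654147 to 17655427 (103). For the haltere disc alone they were 2R 8525117 to 8525859 (53.7) and 3R 2490784 to 2491108 (28.8). For the wing disc alone they were 3R 7022621 to 7022915 and X 6432940 to 6433306, both with a score of 21.5. Leg and haltere discs shared, without the wing disc, 3L 21587368 to 21588339 (122) and 3R 12511177 to 12512393 (112).

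At the pharate stage the 3 appendages shared a smaller part of their regions, and the haltere had the most of its own. Of 36559 merged regions, 12545 (34.3%, 33.8 to 34.8) had a peak in leg, haltere and wing. The haltere alone had 11568 regions (31.6%, 31.2 to 32.1), the wing alone 2389 and the leg alone 2330. Pairs of appendages shared 2531 to 2654 regions each. The pharate haltere list was the longest of the 11, and without it 59.6% of the regions of leg and wing were shared by both. Of pharate wing peaks, 75.3% overlapped a pharate leg peak and 75.6% a pharate haltere peak, against 17.1% and 24.2% in random placements. Over equal numbers of peaks the pharate wing shared 78.3% with the pharate leg and 65.4% with the pharate haltere. The strongest regions of all 3 pharate appendages were 2R 17591413 to 17592605 (score 929) and 2L 478679 to 482819 (919.7). The strongest of the pharate wing alone were X 6433410 to 6433877 (score 355) and 2L 20759298 to 20759791 (162). For the pharate leg alone they were on 3L, at 21978006 to 21980454 (303) and 16270239 to 16271350 (219.6), and for the pharate haltere alone X 2857859 to 2858235 (115) and 3R 19843817 to 19844467 (110.2).

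Between stages, the peaks of an appendage overlapped those of other appendages at the other stage about as often as those of its own. Over equal numbers of peaks, the same appendage shared a mean of 51.9% between disc and pharate stage (49.0 to 53.4 over 3 pairs). Different appendages shared 50.8% (46.3 to 54.7 over 6 pairs). Appendages of one stage shared a mean of 74.8% (65.5 to 82.0 over 6 pairs). Of all wing disc peaks, 64.8% (64.0 to 65.6) overlapped a pharate wing peak, 61.6% a pharate leg peak and 72.4% a peak of the longer pharate haltere list. Regions of all 3 discs had a peak in some pharate appendage in 85.8% of cases (85.1 to 86.4), and regions of 1 disc in 61.9% (60.6 to 63.1). Regions of all 3 discs also had higher best scores (median 24.89 against 6.77), and regions of more lists are wider. These shares were not matched for score or width. Regions of the haltere disc alone overlapped pharate haltere peaks in 52.2% of cases, pharate wing peaks in 21.1% and pharate leg peaks in 17.9%. Regions of the leg disc alone were found in 44.5% in the pharate leg, 56.6% in the pharate haltere and 42.4% in the pharate wing. Regions of the wing disc alone were found in 40.5% in the pharate wing, 32.4% in the pharate leg and 30.8% in the pharate haltere.

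**Figure D2:**
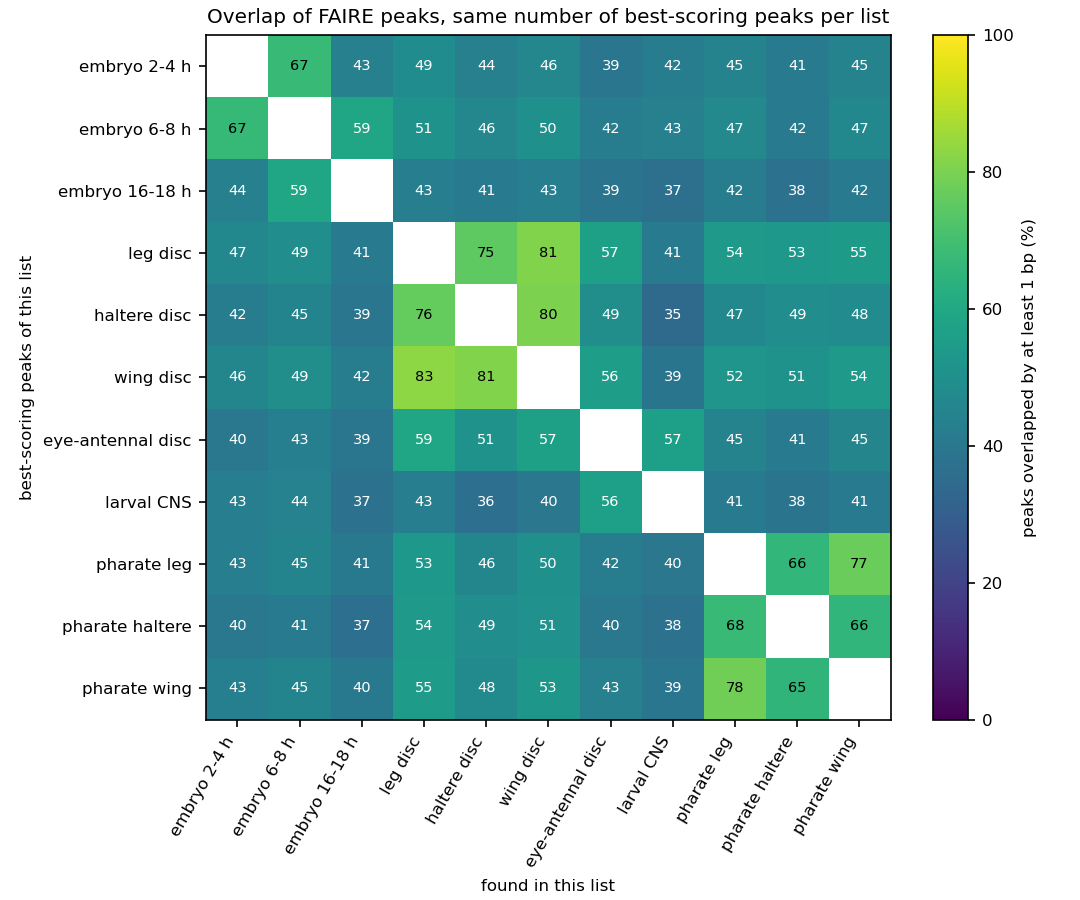
Percent of the 9975 best-scoring FAIRE peaks of each list (rows of the matrix) that overlapped one of the 9975 best-scoring peaks of another list (columns) by at least 1 bp, printed in each cell. The appendages of one stage share from 65.4% to 83.2% of peaks, and the larval CNS shares 34.7% to 42.7% with the 3 appendage discs.

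Eye-antennal disc and CNS were compared with the appendage discs as other larval tissues. The eye-antennal disc shared a mean of 54.9% of peaks with the leg, haltere and wing discs over equal numbers (50.4 to 58.1), and the CNS 38.9% (35.6 to 41.9). Eye-antennal disc and CNS shared 56.5% with each other. Of all wing disc peaks, 42.6% (41.8 to 43.4) overlapped an eye-antennal disc peak and 31.8% (31.0 to 32.6) a CNS peak, against 7.67% and 7.53% in random placements. Regions of all 3 appendage discs overlapped eye-antennal disc peaks in 48.0% of cases and regions of 1 disc in 8.68%, again not matched for score or width.

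Embryonic open chromatin was compared across the 3 stages and with the appendages. The 3 embryo lists merged into 21739 regions, of which 5089 (23.4%, 22.8 to 24.0) had a peak at every stage. Peaks at 2 to 4 h alone made 4658 regions (21.4%), at 6 to 8 h alone 1292 (5.94%) and at 16 to 18 h alone 5722 (26.3%). Of the peaks at 2 to 4 h, 60.2% were found at 6 to 8 h and 44.3% (43.5 to 45.2) at 16 to 18 h. Of the peaks at 16 to 18 h, 53.6% were found at 6 to 8 h. The strongest regions of all stages were 2L 4891669 to 4892398 (score 1298) and 2R 11622400 to 11623881 (1223). At 2 to 4 h alone they were 2R 15548410 to 15549829 (762) and 3L 4696136 to 4697002 (663), at 6 to 8 h alone 3L 12608981 to 12609660 (143) and 2R 2489679 to 2490250 (132), and at 16 to 18 h alone 3R 9646205 to 9646702 (259.95) and X 7590597 to 7591060 (169.9). Over equal numbers of peaks, embryos shared a mean of 45.2% with appendage discs and 42.4% with pharate appendages. Regions of all 3 appendage discs had an embryo peak in 63.6% of cases, and regions of 1 disc in 24.3%, again not matched for score or width. Over all 11 lists, 1983 of 50319 regions (3.94%, 3.77 to 4.11) had a peak in every list and 18820 in 1 list. Their median widths were 1298 and 315 bp. With peaks cut to their central 200 bp before merging there were 1296 regions of every list, and 833 among the better-scoring 50% of peaks.

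Of all 50 kb intervals, 3R 12500001 to 12550000 had the largest summed score of haltere disc peaks absent from the wing disc. The haltere disc had 16 peaks there, 13 of them absent from the wing disc with a summed score of 231, and the leg disc had 18, 15 of them absent from the wing disc. The wing disc had 3 peaks, the CNS 2 and the eye-antennal disc 1. At the pharate stage the haltere had 23 peaks in this interval, 21 of them absent from the wing (summed score 652), the leg 10 and the wing 2. Embryos had 13 peaks at 2 to 4 h, 9 at 6 to 8 h and 6 at 16 to 18 h. By number of absent peaks it was not the first, since X 8000001 to 8050000 had 14 absent of 24, with a summed score of 116. Over all of the arms, 29.2% of haltere disc peaks were absent from the wing disc. For the leg disc against the wing disc, the interval X 17700001 to 17750000 had the largest sum (406), with 12 of 27 peaks absent, and the interval on 3R the next largest (397). In intervals of 100 kb this order turned, with 602 on 3R and 475 on X. For the wing disc against the leg disc it was 2R 8750001 to 8800000 (194), with 9 of 15 absent. For the pharate wing against the pharate leg it was X 6400001 to 6450000 (731), with 6 of 20 absent. No genes were assigned to these intervals.

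**Figure D3:**
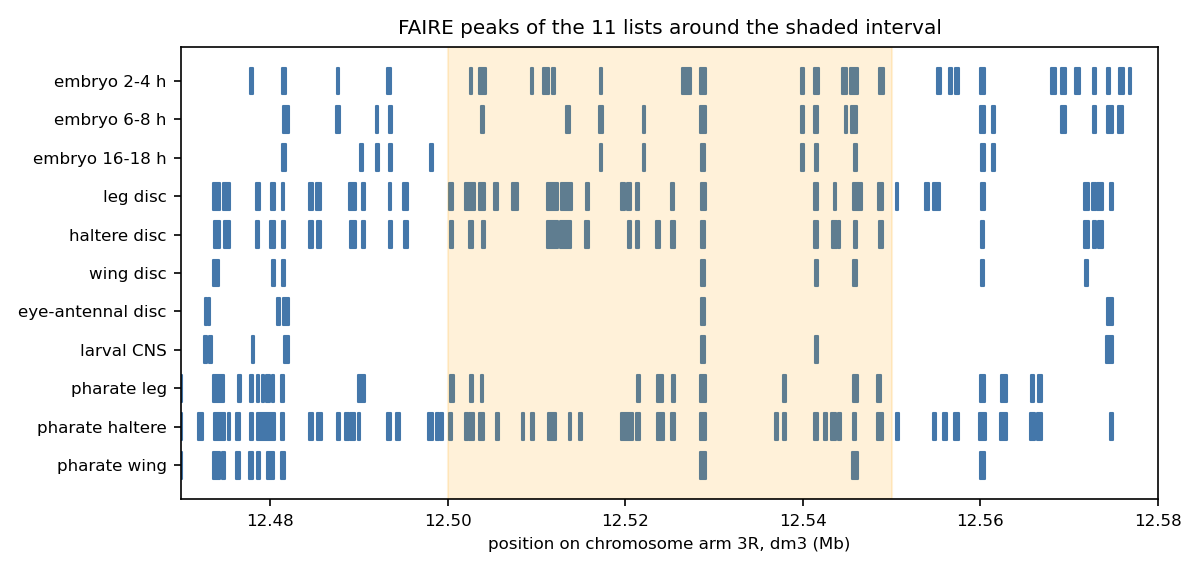
FAIRE peaks of the 11 lists (y axis) around the interval on chromosome arm 3R in dm3 (x axis, Mb), each drawn to scale as a bar from its start to its end. The shaded interval, 12500001 to 12550000, holds 16 peaks in the haltere disc and 3 in the wing disc, and 23 in the pharate haltere and 2 in the pharate wing.

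Haltere and wing discs were compared by RNA-seq to ask which transcripts distinguish these serially related appendages. Ubx, the Hox gene of the posterior thorax, was listed at 332 FPKM in the haltere disc and 6.06 in the wing disc (log2 ratio 5.56). Wing field genes were lower in the haltere disc, where 8 of 23 were at least 2-fold lower and 0 higher (median log2 ratio -0.65, percentile 0 of random lists). Among them were kn (6.44 against 44.967), rn (54.5 against 217), vvl (71.4 against 251) and nub (98.8 against 315). Lists of other genes also had low percentiles in this comparison, with medians of -0.57 for ecdysone response genes (percentile 0.02), -0.41 for leg proximodistal genes (0.945), -0.38 for signalling and compartment genes (0.13) and -0.37 for cell cycle genes (0). Of 7 genes reported as repressed by Ubx in the haltere, 4 were lower and 0 higher (median -1.49, percentile 0). The 4 were kn, vvl, the wing selector vg (110.1 against 314) and the intervein gene bs (45.1 against 129). All 4 are wing field genes too, so these lists are not independent. Markers of other larval tissues were higher in the haltere disc, except tracheal markers, of which 1 of 6, trh, was lower and 0 higher. All 8 fat body markers (median 3.66), 6 salivary gland markers (3.50), 12 midgut markers (3.52) and 5 haemocyte markers (2.97) were at least 2-fold higher, with percentiles of 99.95 to 100.

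Among these markers, the larval serum protein gene Lsp2 was listed at 2428 in the haltere and 188 in the wing disc, and the glue protein gene Sgs7 at 15543 and 1342. The midgut protease gene Jon65Aiii was listed at 1171 and 52.1, and the haemocyte gene He at 166 and 17.5. Muscle and cuticle genes moved with them. Of 21 muscle genes, 15 were higher and 1, twi, lower (median 3.15, percentile 100), with Act57B at 44564 against 3836 and Mlp60A at 10464 against 845. Of 50 cuticle protein genes, 39 were higher and 1, TwdlT, lower (median 3.08), with Cpr47Ee at 236 against 1.21. Odorant-binding protein genes were the chemosensory genes furthest apart, among them Obp44a (319 against 15.2) and Obp56d (7337 against 477), while 17 of 27 genes of that list were within 2-fold. Ribosomal protein genes had 0 of 79 members 2-fold apart and a median of 0.65, and cell cycle genes 0 of 24 and a median of -0.37.

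Genes furthest below the wing disc in the haltere disc included ana (12.4 against 147), beat-IIb (3.66 against 34.3), the FGF ligand gene ths (5.37 against 42.5), Sox100B (1.74 against 15.1) and Wnt2 (39.8 against 192). Antp was listed at 23.9 in the haltere and 61.4 in the wing disc, and Dll, the gene of distal limb fate, at 57.8 and 229. The dorsal compartment gene ap was listed at 539 and 756, and dac at 22.2 and 29.7. The Hox cofactor hth was listed at 292 in the haltere disc and at 0 in the wing disc. In all, 1697 of 8577 genes were at least 2-fold apart, 1329 higher and 368 lower in the haltere disc. Of these, 327 and 142 were listed at 0 in the other disc. The correlation of log2 levels across genes, which are not independent replicates, was 0.907.

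**Figure D4:**
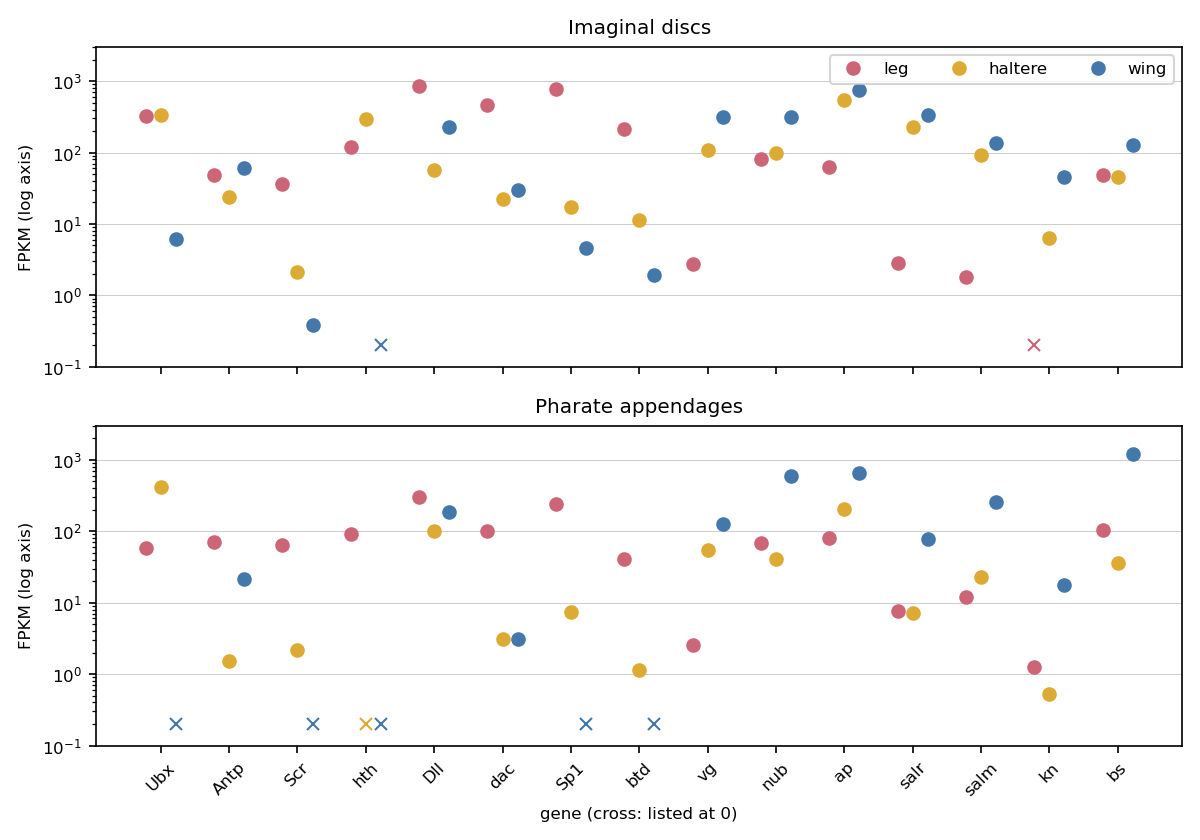
FPKM (log y axis) of 15 patterning genes (x axis) in leg, haltere and wing, for imaginal discs above and pharate appendages below, 1 authors' value per point and crosses for genes listed at 0. Ubx stands at 332 in the haltere disc and 6.06 in the wing disc, Sp1 at 784 in the leg disc and 4.54 in the wing disc, and bs at 1199 in the pharate wing and 36.0 in the pharate haltere.

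Leg and wing discs were compared as ventral and dorsal appendages. They also come from different thoracic segments, and the comparison cannot tell these differences apart. Genes of leg pattern were higher in the leg disc and genes of the wing field lower. Of 15 leg proximodistal genes, 10 were at least 2-fold higher and 1 lower (median 1.17, percentile 100). The leg fate genes Sp1 (784 against 4.54) and btd (217 against 1.91), Lim1 (54.2 against 0.443) and dac (467 against 29.7) were furthest apart. Dll was listed at 866 and 229. Of 22 wing field genes, 17 were lower in the leg disc and 0 higher (median -2.03, percentile 0), among them salr (2.84 against 333), vg (2.76 against 314), salm (1.79 against 136) and mirr (3.89 against 184). The list of genes reported as repressed by Ubx, which holds salr, vg and salm too, had 5 of 6 lower (median -4.23). The transcription factor genes AP-2 (640.05 against 4.08), fd96Ca (296 against 1.53), fd96Cb (1453 against 11.6), lbl (173 against 1.46), H15 (126 against 0.837) and unc-4 (106 against 0.850) were also among the 10 furthest above the wing disc.

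Hox genes of the leg disc included Ubx (319 against 6.06) and Scr (36.4 against 0.386), while Antp was listed at 49.2 and 61.4. Below the wing disc stood Optix (0.976 against 119), tey (0.932 against 92.9), amd (4.31 against 122), pnr (5.47 against 107) and Ect3 (6.62 against 116). The gene nub was listed at 80.5 in the leg disc and 315 in the wing disc, and ap at 61.9 and 756. The proneural gene ato was listed at 134 and 4.46, the signalling genes rho at 92.9 and 21.9 and Wnt6 at 307 and 140.5. Markers of other larval tissues were higher in the leg disc than in the wing disc as well, with medians of 1.79 for fat body, 1.68 for salivary gland, 1.99 for midgut and 1.49 for haemocytes, except tracheal markers, of which 1 of 6 was higher and 0 lower (median -0.14). Muscle genes (14 of 21 higher, median 1.69) and cuticle protein genes (28 of 44 higher and 2 lower, median 1.58) moved with them. In all, 1185 of 8321 genes were at least 2-fold apart, 890 higher and 295 lower in the leg disc, and 191 and 127 of these were listed at 0 in the other disc. With an FPKM minimum of 20 the count was 770.

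Leg and haltere discs come from the same thoracic segment. Their Ubx levels were 319 and 332 FPKM, and hth was listed at 118 in the leg and 292 in the haltere disc. Of 15 leg proximodistal genes, 11 were higher in the leg disc and 1 lower (median 2.06, percentile 100), with Sp1 at 784 against 17.1, dac at 467 against 22.2 and Dll at 866 against 57.8. Of 23 wing field genes, 12 were lower in the leg disc and 0 higher (median -1.03, percentile 0), with salr at 2.84 against 229.7, salm at 1.79 against 93.6, vg at 2.76 against 110.1 and mirr at 3.89 against 129. Antp was listed at 49.2 and 23.9, Scr at 36.4 and 2.14, nub at 80.5 and 98.8 and ap at 61.9 and 539. H15 (126 against 3.37), disco-r (218 against 10.6) and Wnt2 (738 against 39.8) were among the 10 furthest above the haltere disc. Optix (0.976 against 158), tey (0.932 against 115) and tup (2.55 against 68.7) were among the 10 furthest below it.

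Fat body (median -1.82), salivary gland (-1.80), midgut (-2.14) and haemocyte markers (-1.59) had lower medians in the leg than in the haltere disc, with all 8, 6 and 5 fat body, salivary gland and haemocyte markers and 8 of 13 midgut markers at least 2-fold lower. Also lower were 13 of 21 muscle genes (median -1.35) and 41 of 53 cuticle protein genes (-1.76), with 3 cuticle protein genes higher. Of the tracheal markers, dys (81.2 against 15.6) and trh (131 against 35.6) were higher in the leg disc. In all, 1351 of 8529 genes were at least 2-fold apart, 276 higher and 1075 lower in the leg disc, of which 66 and 112 were listed at 0 in the other disc. Across genes the correlation was 0.947, and 0.9495 for leg against wing.

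**Figure D5:**
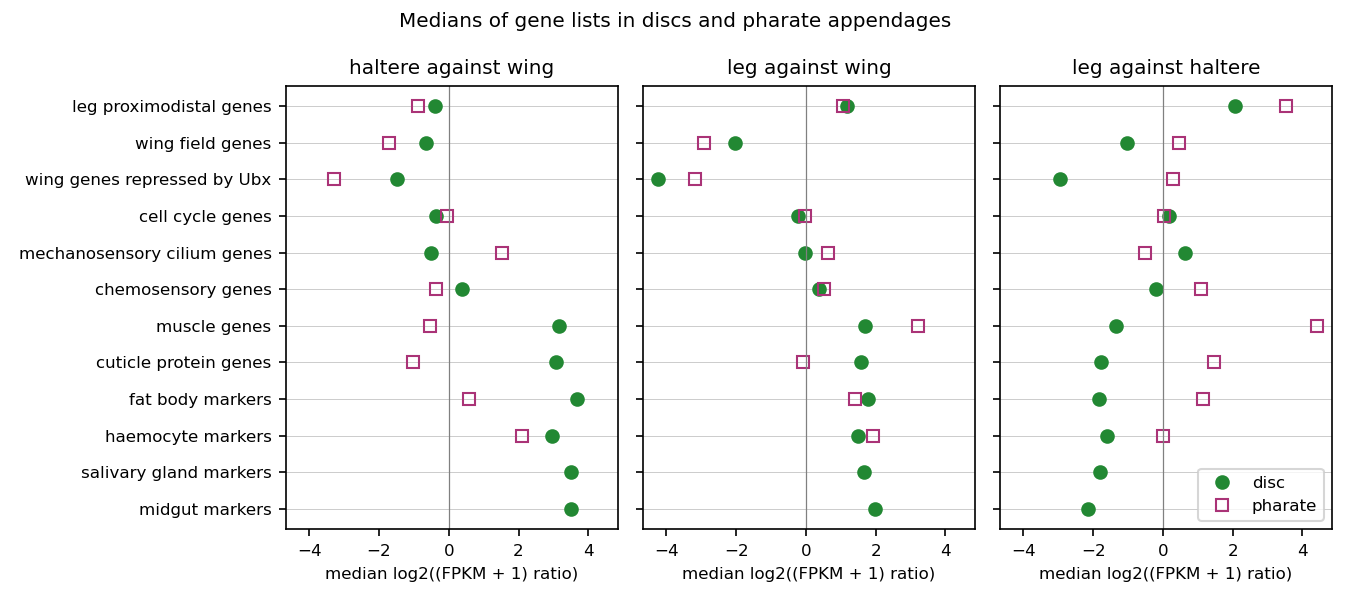
Median log2((FPKM + 1) ratio) (x axis) of 12 gene lists (y axis) for haltere against wing, leg against wing and leg against haltere, with filled circles for discs and open squares for pharate appendages. Medians are over members above 0 in both columns, and salivary gland and midgut markers have no pharate point. Muscle genes stand at 3.15 for haltere against wing discs and at -0.55 at the pharate stage, and at -1.35 and 4.41 for leg against haltere.

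Pharate haltere and wing differed in cuticle and mechanosensory genes beside the wing field genes, among others. Of 22 wing field genes, 19 were lower in the haltere and 0 higher (median -1.72, percentile 0), led by bs (36.0 against 1199), Doc1 (2.32 against 64.1), caup (7.02 against 140.2) and Doc2 (0.923 against 32.1). Of 7 genes reported as repressed by Ubx, 6 were lower (median -3.30, percentile 0), among them kn (0.521 against 17.4), salm (23.0 against 255) and salr (7.08 against 78.4). The wing field list holds kn, salm and salr too, so these lists are not independent. Genes of the mechanosensory cilium were higher in the haltere than in the wing, with 9 of 13 at least 2-fold higher and 0 lower (median 1.51, percentile 99.98). For leg against wing 5 of 13 were higher and 1 lower (median 0.65), and for leg against haltere 2 of 14 were higher, 4 lower and 8 within 2-fold (median -0.52). They included the channel genes nan (21.8 against 2.49) and nompC (88.6 against 21.1) and the ciliary transport genes nompB (64.9 against 10.1) and osm-6 (79.6 against 14.6). Of 38 chemosensory genes, 7 were higher, 14 lower and 17 within 2-fold in the haltere (median -0.36, percentile 6.53), with ppk23 (13.1 against 424) and Obp99c (3477 against 118) furthest apart.

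Ubx was listed at 410.3 in the pharate haltere and at 0 in the pharate wing, and hth at 0 in both. Antp was listed at 1.53 and 21.6, Dll at 101 and 187, dac at 3.07 and 3.11, vg at 55.0 and 127, nub at 41.4 and 599 and ap at 203 and 659. Of 12 ecdysone response genes, 10 were lower in the haltere (median -1.45), with br at 1.69 against 49.2, ImpL2 at 79.2 against 605 and ftz-f1 at 899.97 against 3502. For pharate leg against wing, 7 of 12 were lower in the leg and 0 higher (median -1.11), so this was not particular to the haltere. Of 66 cuticle protein genes, 33 were lower and 15 higher (median -1.03, percentile 0), with Cpr50Ca at 2.50 against 221 and Cpr47Ee at 2427 against 84.9. In the list of chitin, pigment and trichome genes, 7 of 19 were lower and 2 higher (median -0.83), among them the trichome gene mwh (23.4 against 449) and ple, for tyrosine hydroxylase (18458 against 170340). The signalling genes tkv (239 against 1699.9), inv (20.4 against 129) and en (11.3 against 61.0) were lower.

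Of 21 muscle genes, 9 were lower and 1 higher in the haltere and 11 within 2-fold (median -0.55), and the muscle myosin gene Mhc was listed at 0 in all 3 pharate columns. Haemocyte markers were higher in the haltere in 4 of 4 measured (median 2.09), with srp at 87.6 against 12.4 and Hml at 239.96 against 44.3. Among the 10 genes furthest apart on either side were spz2 (461 against 1.103) and Sodh-1 (714 against 2.96), higher in the haltere, and Hsc70-2 (23.3 against 4473) and rho-6 (18.9 against 2164), lower. In all, 3518 of 8990 genes were at least 2-fold apart, 1829 higher and 1689 lower in the haltere, of which 299 and 158 were listed at 0 in the other column. The correlation across genes was 0.829.

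Pharate leg and wing differed in muscle and wing field genes, among others. Of 20 muscle genes, 15 were higher in the leg and 1 lower (median 3.22, percentile 100), with Mlp60A at 31837 against 1040.4, Act79B at 369679 against 13826 and TpnC41C at 49491 against 1997. Of 21 wing field genes, 15 were lower and 2 higher in the leg (median -2.91, percentile 0), with vg at 2.59 against 127, salm at 12.2 against 255 and rn at 1.72 against 50.5. Of 9 leg proximodistal genes above 0 in both, 5 were higher and 1 lower (median 1.07), led by dac (101 against 3.11) and drm (166 against 21.8), while Dll was listed at 298 and 187. Another 5 members were listed at 0 in one column, among them Sp1 (240.2 in the leg) and btd (41.0 in the leg), at 0 in the wing. Cuticle protein genes went both ways, 24 of 64 higher and 21 lower (median -0.09), with Cpr64Ad (3488 against 33.5), Ccp84Ae (2904 against 37.9) and Edg91 (1136 against 14.8) furthest above the wing.

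The tyrosine hydroxylase gene ple (10069 against 170340) and Ddc (1577 against 16429), both of pigment and cuticle hardening, were lower in the leg. Wnt6 was listed at 257 in the leg and 27.8 in the wing, the glial transporter gene Eaat1 at 1918 and 270.01 and the chordotonal channel gene iav at 28.5 and 2.42. Of 44 chemosensory genes, 13 were higher and 5 lower (median 0.53), with Or47a at 924 against 41.8. Ubx was listed at 59.0 in the leg and at 0 in the wing, hth at 90.1 and at 0, Antp at 71.0 and 21.6, nub at 68.4 and 599 and ap at 79.3 and 659. Fat body markers (4 of 6 higher, median 1.40) and haemocyte markers (3 of 3 higher, median 1.93) were higher in the leg as well. In all, 3276 of 9011 genes were at least 2-fold apart, 1952 higher and 1324 lower in the leg, of which 296 and 275 were listed at 0 in the other column. The correlation across genes was 0.860.

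Pharate leg and haltere differed in muscle, leg pattern and chemosensory genes. Of 19 muscle genes, 18 were higher in the leg and 1 lower (median 4.41, percentile 100), with bt at 2630.5 against 72.5, Prm at 47124 against 1478 and Mlp84B at 12938 against 506. Of 13 leg proximodistal genes, 11 were higher and 1 lower (median 3.52, percentile 100), with Sp1 at 240.2 against 7.37, dac at 101 against 3.07 and Lim1 at 33.1 against 0.480. Of 41 chemosensory genes, 21 were higher in the leg and 5 lower (median 1.101, percentile 100), among them the pheromone channel gene ppk23 (403 against 13.1), Obp19b (1046 against 37.6) and CheA7a (4012 against 209). Of 63 cuticle protein genes, 35 were higher and 11 lower (median 1.48), while TwdlT stood at 388 in the leg and 33853 in the haltere.

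Hox genes differed in both directions, with Antp at 71.0 against 1.53 and Scr at 64.2 against 2.18, but Ubx at 59.0 against 410.3. Of 19 wing field genes, 6 were higher and 5 lower in the leg (median 0.47), with vg (2.59 against 55.0) and rn (1.72 against 18.5) lower and ct (39.0 against 7.73) and caup (34.0 against 7.02) higher. Dll was listed at 298 and 101, nub at 68.4 and 41.4, ap at 79.3 and 203 and hth at 90.1 and 0. The gap gene hb (88.6 against 2.50) and the BMP antagonist sog (279 against 29.3) were higher in the leg, and spz2 (5.88 against 461) lower. Fat body markers were higher in the leg in 4 of 6 and lower in 1 (median 1.14), and 4 haemocyte markers were within 2-fold. In all, 2835 of 9044 genes were at least 2-fold apart, 1543 higher and 1292 lower in the leg, of which 169 and 268 were listed at 0 in the other column. The correlation across genes was 0.850.

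Between 2 to 4 h and 6 to 8 h, embryos showed lower maternal and early patterning transcripts and higher Hox transcripts. Of 17 maternal genes, 12 were at least 2-fold lower at 6 to 8 h and 0 higher (median -1.72, percentile 0), with pgc at 16.8 against 372, nos at 11.1 against 226 and bcd at 133 against 282. Of 16 gap and pair-rule genes, 12 were lower and 1 higher (median -1.69, percentile 0), with eve at 21.5 against 597, prd at 21.3 against 416 and ftz at 98.8 against 769. The dorsal gene zen (2.33 against 555), the cellularisation genes Sry-alpha (104 against 3821) and slam (110.01 against 3917) and the mesoderm gene twi (112 against 841) were lower. Of 7 Hox genes above 0 in both, 6 were higher (median 3.30, percentile 99.99), with Ubx at 147 against 8.84, Scr at 133 against 8.99 and abd-A at 299.8 against 26.7.

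Of 3 neuronal genes measured at both stages, 1 was higher and 1 lower at 6 to 8 h (median -0.45). Single neural genes that stood higher were elav (469 against 65.9), sens (220.4 against 1.89) and the glial gene repo (48.2 against 0.923). The tracheal gene trh (149.5 against 2.35), the cell cycle inhibitor dap (1872 against 56.9) and the myoblast gene lmd (365 against 1.48) were higher too, and Mhc was listed at 29.4 and 3.98. Among the 10 furthest below 2 to 4 h were Bsg25A (6.09 against 2560.03), term (12.2 against 4041) and SNCF (22.1 against 5676). In all, 3693 of 8244 genes were at least 2-fold apart, 2139 higher and 1554 lower at 6 to 8 h, of which 556 and 89 were listed at 0 at the other stage. The correlation across genes was 0.797.

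Between 6 to 8 h and 16 to 18 h, genes of differentiated muscle, cuticle and neurons stood higher and cell cycle genes lower. All 24 cell cycle genes were at least 2-fold lower at 16 to 18 h (median -3.07, percentile 0), with aur at 8.36 against 277 and Mcm3 at 33.5 against 575. Of 19 muscle genes above 0 at both stages, 17 were higher and 1 lower (median 6.87, percentile 100), with Mf at 2374 against 7.57 and Tm2 at 4587 against 20.8, while Mhc was listed at 29.4 at 6 to 8 h and at 0 at 16 to 18 h. Of 43 cuticle protein genes, 38 were higher and 1 lower (median 7.61), with TwdlF at 13930.4 against 22.8, and another 45 were listed at 0 at one stage. Of 10 neuronal genes, 8 were higher and 1 lower (median 6.04), among them the synaptic vesicle genes n-syb (432 against 2.23) and Syt1 (265 against 1.45) and Gad1, for the enzyme of GABA synthesis (148 against 1.07), while elav was listed at 208 and 469.

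Chitin deacetylase genes serp (2424 against 14.5) and verm (5183 against 32.4) were higher at 16 to 18 h. Of 14 ecdysone response genes, 9 were higher and 2 lower (median 3.08), with Eip78C at 136 against 3.14 and Eip74EF at 110.4 against 3.41. Of 18 signalling and compartment genes, 13 were lower and 0 higher (median -2.26, percentile 0), with Dl at 52.5 against 623 and en at 29.0 against 277. The proneural gene sens (3.29 against 220.4) and the Bearded family genes Brd (8.46 against 3142), Tom (36.6 against 6167) and BobA (8.86 against 2286) were lower. Ubx was listed at 102 and 147, bcd at 53.0 and 133, eve at 17.3 and 21.5, zen at 1.57 and 2.33 and twi at 22.003 and 112. In all, 6691 of 10173 genes were at least 2-fold apart, 3532 higher and 3159 lower at 16 to 18 h. Of the higher genes 1365 were listed at 0 at 6 to 8 h, and of genes above 0 at both stages 2167 were higher and 2973 lower, while with an FPKM minimum of 20 these were 2810 and 2928, so that the balance of directions depended on which genes were counted. The median ratio over all genes was -0.14 and the correlation across genes 0.480.

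Between 2 to 4 h and 16 to 18 h, more genes were at least 2-fold apart than in any other of the 9 comparisons. Muscle genes were higher in 15 of 16 and lower in 1 (median 7.82), with wupA at 6439.6 against 2.89 and Mlp60A at 15092 against 8.40. Tracheal markers were higher in 6 of 7 and lower in 1 (median 4.71), with Gasp at 8121 against 11.2, and ecdysone response genes in 11 of 14 with 0 lower (median 3.59), with ImpE1 at 202 against 0.862. All 15 gap and pair-rule genes above 0 at both stages were lower (median -3.41, percentile 0), with prd at 2.62 against 416, gt at 6.51 against 531 and eve at 17.3 against 597. Maternal genes were lower in 16 of 17 (median -2.39) and cell cycle genes in 23 of 24, with 1 higher (median -3.38). Between these stages bcd was listed at 53.0 and 282, zen at 1.57 and 555, twi at 22.003 and 841, Ubx at 102 and 8.84, elav at 208 and 65.9, and Mhc at 0 and 3.98. In all, 7615 of 10190 genes were at least 2-fold apart, 4199 higher and 3416 lower at 16 to 18 h. Of genes above 0 at both stages 2027 were higher and 3205 lower, and 2172 of the higher genes were listed at 0 at 2 to 4 h. The median ratio over all genes was 0.12 and the correlation 0.458. Every named ratio of at least 2-fold in the 9 comparisons kept its direction when the median of its comparison was subtracted. This was bound to be so, since the subtraction shifted log2 ratios by at most 0.144.

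Disc and pharate levels of the same appendage come from separately normalised tables, so ratios between them are given as a description only. Cell cycle genes were listed lower at the pharate stage in 22 of 22 genes of the wing (median log2 ratio of pharate over disc -5.08), 23 of 24 of the haltere (-5.35) and 22 of 23 of the leg (-5.18). Ribosomal protein genes were lower in 76 of 78 for the wing (-2.03), 77 of 78 for the haltere (-2.08) and 77 of 78 for the leg (-1.62). Neuronal genes were higher in 6 of 6 for the wing (3.14), 5 of 6 for the haltere (4.46) and 8 of 8 for the leg (3.62), and glial genes in 5 of 6, 6 of 6 and 6 of 6. Muscle genes were higher in 16 of 18 and lower in 1 for the leg (5.45), higher in 15 of 19 for the wing (3.43), and higher in 7 and lower in 4 of 17 for the haltere (0.55). The medians over all genes were -0.07 for the wing, -0.29 for the haltere and -0.18 for the leg.

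Some abundant genes were listed at 0 in a single column. In the wing disc 29 genes were at 0 with more than 100 FPKM in both other discs, in the pharate leg 63 and at 2 to 4 h 46, and without snoRNA genes these were 27, 63 and 20. Chosen after their values were seen, examples are the wing gene sd (169.7 in the leg and 153 in the haltere disc, 0 in the wing disc) and arm (817 in the pharate haltere and 1470.3 in the pharate wing, 0 in the pharate leg). The gene zip was listed at 0 in all 9 columns. A value of 0 for such genes, hth in the wing disc among them, was kept as deposited and cannot be read as absence of transcript.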

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

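The tests of other-tissue RNA, of scaling, of haltere identity and of the third disc in between in this part were chosen only after the results were seen.

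Among the gene lists, and among Ubx, Antp, Dll, dac, vg, nub, ap, hth and the genes with the 10 largest or 10 smallest ratios of a comparison, the medians of 3 lists and 13 genes stood on opposite sides in the disc and pharate comparisons of the same 2 appendages, at least 2-fold each way; single pooled values carry no spread, and these differences were not tested. Apart from the genes named here, a gene was searched only for the pair of appendages in which its ratio was among these 10, in discs or at the pharate stage. Other genes and other pairs were not searched, and more may change sides. Muscle genes had a median log2 ratio of leg against haltere of -1.35 in discs and 4.41 at the pharate stage, a difference of 5.76. Cuticle protein genes went from 3.08 to -1.03 for haltere against wing (-4.11) and from -1.76 to 1.48 for leg against haltere (3.24). Fat body markers went from -1.82 to 1.14 for leg against haltere (2.96). Among the genes searched for each pair, TwdlT (6.70), spz2 (8.87), Cpr47Eg (-7.42) and CG10962 (-9.14) changed sides for haltere against wing. Pharate minus disc differences are in brackets. For leg against wing these were Ect3 (5.35), pnr (5.52), CG12378 (-8.88) and CG6414 (-13.06). For leg against haltere they were the muscle genes bt (6.38) and abba (6.15), spz2 (-8.78), CG11321 (7.92), CG11835 (6.58), CG9297 (6.25) and CG6414 (-6.23). Beyond the 6 arms, in sequence that no comparison used, the eye-antennal disc list held 455 peaks and the CNS list 211, while the other 9 lists held 0.

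Markers of larval fat body, haemocytes, salivary gland and midgut were at least 2-fold higher in the haltere than in the wing disc in 31 of 31 genes (100%, exact 95% interval 88.8 to 100; median log2 ratio 3.47, quartiles 2.99 and 3.69). A general scale difference of the haltere column as the whole cause is argued against by the median over all genes, 0.0398. Depth was not tested by this median, because the deposited columns already had close upper quartiles (162 in the haltere and 159 in the wing disc). Haltere identity alone is argued against by the leg disc, where the same markers stood 1.66 above the wing disc (quartiles 1.495 and 1.844). Tracheal markers, of another larval tissue and not among the 31, were at least 2-fold higher in 0 of 6 and lower in 1. RNA of other larval tissues in the disc preparations and expression of the same genes within the discs cannot be told apart, because the share of markers that were higher restates the difference itself. The most abundant marker, Sgs7, reached 15543 FPKM in the haltere disc, and 23 of the 31 markers had an FPKM of at least 5 in the wing disc as well, so the wing disc is not free of them. All 31 markers stood in the order haltere, leg, wing. Of 617 genes at least 4-fold higher in the haltere than in the wing disc and above 0 in all 3 discs, 590 (95.6%) had the leg disc in between. For the 5 other ordered pairs of discs, which had only 12 to 150 such genes, the third disc lay in between in 24.0% to 69.1% of them. These genes were selected by the difference, and whether the muscle and cuticle differences between discs share an origin with the markers was not tested and stays open.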

How the results depend on the processing

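The leaving out of each list, the restriction to genes above 0, the keeping of repeated names, the inclusion of genes listed at 0 in list medians and the intervals of 25 and 100 kb were chosen only after the results were seen. With peaks cut to their central 200 bp before merging, regions of all 3 discs made 45.5% and of all 3 pharate appendages 24.3%. By this cut 1296 regions were in all 11 lists and 7600 in 1 disc. With an overlap of at least 50%, 63.3% of wing disc peaks were found in the pharate wing. The eye-antennal disc had 39.0% of them and the CNS 26.8%. Of peaks at 2 to 4 h, 43.2% were found at 16 to 18 h. Among the better-scoring 50% of each list these were 51.8% for discs, 62.9% for the pharate wing, 46.3% for the eye-antennal disc, 29.5% for the CNS, 41.6% for 16 to 18 h and 833 regions, with 90.0% of wing disc peaks in the haltere disc and 3532 regions in 1 disc. Among equal numbers of peaks, regions of all 3 made 53.4% in discs and 39.2% at the pharate stage, wing disc peaks were found in 53.8% in the pharate wing, 81.1% in the haltere disc, 55.5% in the eye-antennal disc and 38.7% in the CNS, and 3676 regions were in 1 disc. Regions of both remaining lists made 65.8%, 64.9% and 67.6% without the leg, haltere or wing disc list, and 43.7%, 59.6% and 43.9% without the pharate leg, haltere or wing list, where fewer lists have to share a region. For the values under the other settings the cause was not tested. Sequences beyond the arms could move none of the 9 peak results, since only the eye-antennal disc and CNS lists held peaks there.

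With an FPKM minimum of 20, which leaves fewer genes, 770 genes were at least 2-fold apart between leg and wing discs, while the other 8 counts stayed within 1.5 times. All 9 counts did so under pseudocounts of 0.1 and 5, without a filter, centred on the median, above 0 in both columns and with repeated names. Of 780 ratios of at least 2-fold of genes taken by the naming rule, 33 were under 2-fold with a pseudocount of 5 and 7 with centring. All 780 kept their direction under pseudocounts 0.1 and 5 and centring, which was fixed in advance. A pseudocount cannot change the sign of a ratio, and centring shifted log2 ratios by at most 0.144. Including genes listed at 0 left 119 list medians as they were, changed 73 in size, for example to -5.52 for genes reported as repressed by Ubx between leg and wing discs, and reversed 4: maternal genes for pharate leg against wing (-0.0294), haemocyte markers for pharate leg against haltere (-0.17), chemosensory genes for 16 to 18 h against 6 to 8 h (2.86) and proneural genes for 16 to 18 h against 2 to 4 h (-1.86). The interval on 3R had the largest summed score for haltere against wing disc at 25, 50 and 100 kb. No paired analysis was possible because each tissue had 1 pooled value. Low-scoring peaks were those least often found in a second list. The number of reads behind each list was not known, so no effect of depth on the shares found in 1 tissue alone could be tested.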

Other observations

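The tests of chromosome 4 and of the interval on 3R in this part were chosen only after the results were seen.

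Eye-antennal genes were not described above as a group, and between leg and wing discs 2 of 4 were higher and 2 lower in the leg disc (median log2 ratio -0.87). Optix, a gene of eye development, was listed at 0.976 FPKM in the leg disc, 158 in the haltere and 119 in the wing disc, and eya at 2.50, 25.5 and 27.4, while ato stood at 134, 8.85 and 4.46 and so at 52.1, 33.3 and 20.8. At the pharate stage eya was listed at 20.1 in the leg, 0.648 in the haltere and 1.87 in the wing, and so at 82.6, 6.55 and 6.23. Optix stood at 268 in the pharate haltere and 46.5 in the pharate wing. In embryos, all 6 eye-antennal genes above 0 at both stages were at least 2-fold higher at 6 to 8 h than at 2 to 4 h (median log2 ratio 2.31), with ato at 161 against 10.9 and ey at 43.9 against 3.90.

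Neuronal genes of the pharate appendages went both ways between haltere and wing, with 5 of 11 higher and 3 lower in the haltere (median 0.76). The microtubule gene futsch was listed at 117 against 21.5 and nrv3 at 1127 against 288, while Syx1A stood at 51.2 against 274. Glial genes were higher in the pharate leg than in the wing in 3 of 6 (median 1.24), with repo at 64.0 against 14.5.

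The 6 appendage lists held 41 to 45 peaks on chromosome 4, and the eye-antennal disc, CNS and embryo lists 139 to 192. Strain is argued against as the cause, since the CNS list, of the same strain as the appendages, held 157. Lower depth or a stricter threshold is argued against by the eye-antennal disc peaks on chromosome 4, which were found in appendage lists less often than peaks of like score on the other arms, by 34.1 percentage points or more in each of 6 lists, against at most 12.8 in the other 4 lists. Tissue and a difference in peak calling or control between groups of lists cannot be told apart, because the settings and the control behind each list were not known. The lists were not all called or filtered alike. The shortest peak was 143 to 149 bp in the leg, haltere and wing disc lists and 250 bp in every other list. The eye-antennal disc and CNS lists held 455 and 211 peaks beyond the arms, and the embryo and appendage lists 0. The splits by shortest peak and by peaks beyond the arms are not that of the chromosome 4 counts. Peak numbers missing from a list were 87 to 142 in the appendage lists and 659 to 1297 in the embryo lists. None was missing in the eye-antennal disc and CNS lists. This trace of processing does set the appendage lists apart from the others. Whether processing caused the chromosome 4 counts was not tested and stays open.

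The interval on 3R between 12500001 and 12550000 held the largest summed score of haltere disc peaks absent from the wing disc, 231. Absence was then reassigned at random among peaks of like score, in 20 score strata. Of 10000 reassignments, 0 had an interval with as large a sum, and the highest reached 194. Peaks were reassigned singly, as if neighbouring peaks were absent independently of each other, which was not tested. Chance placement of peaks that are absent together is therefore not excluded. Among the 9975 best-scoring peaks of both lists, the same interval had the largest sum, 214. That argues against the shorter wing disc list as the whole cause. With the same limit, 0 of 10000 reassignments of these peaks had an interval with as large a sum, the highest reaching 176. A difference between haltere and wing tissue stays open as a hypothesis, found and tested on the same data. The pharate lists, which had 21 of 23 haltere peaks absent from the wing there, were seen before the tests were chosen.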
